A study of Mus musculus with 86 samples.

How the data were processed

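Total RNA from 8 tissues of C57BL/6J mice, labelled Young, Old, STDR or LTDR, was sequenced as 86 libraries made with TruSeq RNA v2. Organs were cut into pieces and frozen before RNA extraction, per the labels, and restricted animals received their food once daily in the morning. The labels give female sex for the restriction experiments only. The deposited values are counts of reads per gene name, 1 table per library, with 35006 gene names, of which 32808 had a count in any library. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, aligned to the mm9 mouse assembly with TopHat2 2.1.0 and Bowtie, and counted with HTSeq 0.11.2. The annotation and the strand setting are not given in the sources used here. Gene names were used as deposited and no coordinates are given, since the reference at hand was of another assembly.

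Each table also held the reads that fell outside annotated genes or on several genes. The share of reads outside genes is their number divided by all uniquely aligned reads of a library. CPM values were scaled further by trimmed mean of M values (TMM) factors, except those of sex-linked genes and of markers of other organs. The depth was 4261227 to 29112992 counts per library, with 16078 to 26129 genes counted at least once. Among 76 pairs of libraries of a group in a tissue 0 were identical, and pairs differed by a chi-square per degree of freedom of 6.91 to 246, against 1 for counting error alone. Xist and genes of the Y chromosome were read as a check of sex.

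Each tissue was fitted on its own with the 4 conditions as groups, in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 13650 genes in Blood, 17631 in Brain, 16435 in Heart, 16616 in Kidney, 14476 in Liver, 17745 in Lung, 15986 in Muscle and 16567 in Skin. Old was compared with Young, LTDR with Old, STDR with Old and LTDR with STDR by quasi-likelihood F tests, two-sided. P-values were adjusted by Benjamini and Hochberg within a tissue and comparison, with a threshold of 0.05. The SE of a log2 fold change comes from the same fit.

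Among the 54 gene lists written before the data were examined, those with at least 5 detected members were tested in each tissue by camera with a preset correlation of 0.01, and again with an estimated correlation, in 411 tests per comparison. Members past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Of the 202, 182 and 173 list calls for Old against Young, LTDR against Old and STDR against Old, 0, 3 and 2 held with an estimated correlation. With fry, 83, 13 and 42 of them held. Interferon response genes were the list of the main question. A second model of all tissues together tested whether the change of a gene differed between tissues, over 21368 genes, with all libraries taken as independent.

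Genes opposed between age and restriction were those past the threshold in both comparisons with opposite signs. Both comparisons share the Old libraries, so counts of all groups were simulated from the Old means, with no gene changed, for reference. Genes raised with age in at least 2 other tissues were tested as a list in each tissue by camera.

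The genes named were chosen by a rule written before the data were examined. In each tissue and comparison it takes the 12 largest rises and the 12 largest falls past the threshold, with a mean of at least 5 CPM in the higher group, no overlap between the groups, and no predicted, unnamed or sex-linked genes. It adds up to 4 members of each list past the camera test, a panel of 12 genes in every tissue, and the first 15 genes changed in the most tissues per direction and comparison. The panel was Stat1, Irf7, Ifit3, Oasl2, Bst2, H2-K1, Cd74, C4b, Tlr7, Cdkn1a, Fkbp5 and Per2. Markers of other organs and genes named beside a count of 5 or fewer were chosen after their values were seen.

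Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no filter on low counts, a block for the replicate number, leaving out each library in turn, fry and an estimated correlation for lists, and limma voom with quality weights for differences between tissues. After the data were seen, the logarithm of the share of reads outside genes was added as a covariate, and Kidney and Muscle were fitted without libraries holding at least 75 genes 4-fold above every other library of the tissue. Differences between tissues were also tested with same-numbered libraries of a condition as a block and by limma voom without quality weights. The pipeline was tested on simulated counts with 200 changed genes per tissue. No library was left out of the fits reported first.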

Results

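RNA-seq read counts per gene were deposited for 86 libraries from 8 tissues of C57BL/6J mice, Skin, Muscle, Blood, Brain, Lung, Heart, Kidney and Liver. Young mice were 4 months old and Old mice 22 months old, both with free access to food. Mice on long-term dietary restriction (LTDR) received 70% of that food from 4 to 22 months of age. Mice on short-term dietary restriction (STDR) were restricted for the last 2 months before the same age. Heart, Kidney and Liver had 3 libraries in each condition. Blood and Skin had 3 Young, 2 Old, 3 STDR and 2 LTDR libraries. Brain had 3 Young libraries and 2 in each other condition, Lung had 2 Old libraries and 3 in each other condition, and Muscle had 3 Young, 2 Old, 2 STDR and 3 LTDR libraries. By tissue, counts in named genes per library were 5892768 to 10998050 in Blood, 8774226 to 21352304 in Brain, 7131440 to 15067931 in Heart and 7550518 to 29112992 in Kidney.

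The remaining totals were 6465807 to 20727328 in Liver, 7164418 to 15224175 in Lung, 5419415 to 10460958 in Muscle and 4261227 to 10191940 in Skin. Globin transcripts took 35.9 to 66.6% of the Blood counts. Uniquely aligned reads outside annotated genes made up 4.99 to 83.4% of a library. All libraries held Xist, the transcript of the inactive X chromosome, at 69.5 to 2630 CPM (counts scaled to a common library total). The Y-linked Eif2s3y was at 11.8 CPM in Skin STDR 2 and had no count in any other library. The labels number the libraries of a group without stating that each came from another animal, so the p-values measure only the spread between these libraries, which may be partly technical.

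Transcripts of other organs stood out in single libraries. Testis-specific Ldhc was at 595 CPM in Skin STDR 2 and at most 0.75 CPM in any other Skin library. Albumin (Alb) of hepatocytes was at 2600 CPM in Brain Young 2, 6430 CPM in Kidney STDR 1 and 7580 CPM in Muscle Young 1. The pituitary hormone prolactin (Prl) was at 4400 CPM in Brain Old 2, and the thymocyte recombinase Rag1 at 532 CPM in Blood Young 2 and 496 CPM in Lung Young 2. Kidney Young 1 held Defa24 of the gut at 629 CPM and Chga of endocrine cells at 225 CPM. Muscle Old 1 held salivary Psp at 36000 CPM, Muscle STDR 1 held Dmbt1 of the gut at 5540 CPM, and Muscle Young 2 held neuronal Snap25 at 99.1 CPM. Fast skeletal myosin Myh4 reached 12300 CPM in Skin Young 2. Reads assigned to Lars2 took 1.78 to 33.8% of the counts of the Young libraries of Kidney, Liver, Lung, Muscle and Skin, and at most 3.36% of any other library.

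**Figure D1:**
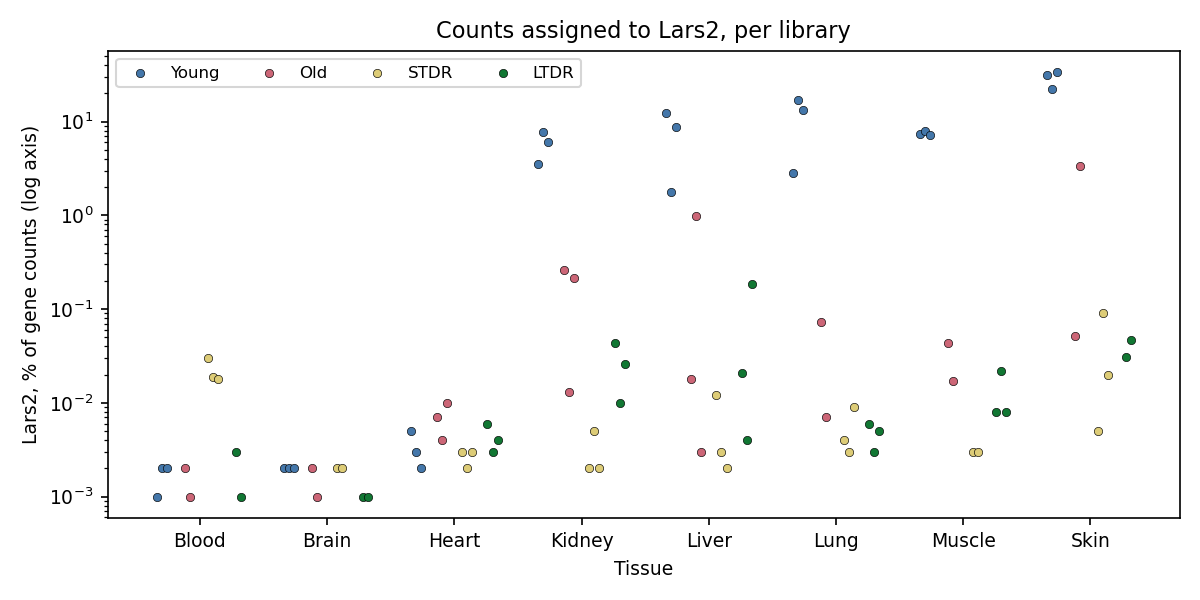
Share of each library's gene counts assigned to Lars2, in percent on a log axis, for the 86 libraries by tissue. Points are libraries coloured by condition; the Young libraries of Skin sit between 22.3 and 33.8%.

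The comparison of Old with Young mice addresses which transcripts differ with age in each tissue. Immune transcripts rose in several tissues. Trem2, a receptor of macrophages and microglia, Naip2, a sensor of bacterial proteins, and Unc13d, which primes cytotoxic granules, each rose in 5 of 8 tissues. The macrophage lysosomal protein Cd68 and the oxidase subunit Cybb rose in Brain, Kidney, Liver and Lung. In Kidney Trem2 (log2 fold change 3.37, SE 0.51, adjusted p = 0.00597) and Cd68 (2.52, SE 0.42) were among them. Genes passing the test numbered 4815 in Brain (2156 up and 2659 down), 2133 in Liver (904 and 1229), 1631 in Blood (1234 and 397) and 1614 in Kidney (1149 and 465). Lung had 826 (292 and 534), Skin 311 (180 and 131), Muscle 7 and Heart 1. Across tissues, 964 genes rose and 713 fell in 2 or more. A test of the difference between tissues, with libraries taken as independent and no covariate, passed for 7566 of 21368 genes. It passed for 3822 by limma voom without quality weights, added after the data were seen.

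In Brain, genes of microglia and of antigen presentation were higher in Old libraries. Forebrain genes were far lower there, so age and brain region were not separated. Itgax (log2 fold change 4.39, SE 0.30, adjusted p = 0.000444), an integrin of activated microglia, was at 6.23 ± 0.373 CPM (SD, n = 2) in Old and 0.287 ± 0.0895 CPM (SD, n = 3) in Young libraries. Clec7a (log2 fold change 4.18, SE 0.35, adjusted p = 0.000516), a fungal glucan receptor, and Lyz2 (3.67, SE 0.28), the macrophage lysozyme, rose too. Of the interferon response genes, 46 of 58 measured members rose and 1 fell (50 and 1 adjusted over the list alone), among them Gbp2 (2.36, SE 0.17), Oasl2 (2.69, SE 0.36) and Stat1 (0.95, SE 0.15). In the list of class II presentation, 5 of 10 measured members rose (8 adjusted over the list alone), with H2-Ab1 (3.37, SE 0.40) and Cd74 (2.94, SE 0.45). Of the macrophage markers, 19 of 23 measured members rose (20 adjusted over the list alone), and of the complement genes, 8 of 14 measured members rose (10 adjusted over the list alone), with C1qa (1.39, SE 0.24) and C4b (1.78, SE 0.37). Gfap (log2 fold change 1.57, SE 0.13, adjusted p = 0.000516), the filament protein of astrocytes, rose as well. In the erythroid list, 9 of 14 measured members rose and 1 fell (11 and 1 adjusted over the list alone), and the pituitary transcripts Prl (8.42, SE 2.37) and Cga were carried by Old 2.

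Transcription factors of the embryonic and adult forebrain fell in the Old Brain libraries. Tbr1 (log2 fold change -5.59, SE 1.25, adjusted p = 0.0204) was at 0.888 ± 0.05 CPM (SD, n = 2) in Old and 43.2 ± 6.21 CPM (SD, n = 3) in Young libraries, and Foxg1 (-5.54, SE 1.19), Satb2 (-4.98, SE 1.06) and Fezf2 (-5.10, SE 1.36) fell alike. The striatal receptors Drd1a (-4.81, SE 1.07) and Adora2a (-4.86, SE 1.15) fell with them. Of the neuron markers, 1 of 22 measured members rose and 11 fell (1 and 13 adjusted over the list alone), including Slc17a7 (-2.83, SE 0.24), the glutamate transporter of cortical synapses, and Snap25 (-0.94, SE 0.09). The immediate early genes, switched on by neuronal activity, had 1 up and 14 down of 28 (2 and 15 adjusted over the list alone), with Egr1 (-4.10, SE 0.37) and Arc (-3.26, SE 0.28). Of the cholesterol synthesis genes, 10 of 24 measured members fell (11 adjusted over the list alone), with Hmgcr (-1.13, SE 0.12). The count was 1988 without Old 2, the library with the pituitary transcripts.

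In Kidney, markers of immune cells and of injury were among the rises (n = 3 per group). Igkc (log2 fold change 5.48, SE 0.76, adjusted p = 0.00582), the kappa light chain of antibodies, was at 485 ± 245 CPM (SD, n = 3) in Old and 10.9 ± 5.83 CPM (SD, n = 3) in Young libraries. Of the T cell markers, 17 of 20 measured members rose (20 adjusted over the list alone), with Cd3d (2.94, SE 0.41), and of the macrophage markers, 21 of 23 measured members rose and 0 fell (21 and 1 adjusted over the list alone), with Mrc1 (2.17, SE 0.34). Chemokines and cytokines included Ccl7 (4.52, SE 0.73) and Tnf (4.41, SE 0.66), in a list where 15 of 27 measured members rose and 0 fell (20 and 1 adjusted over the list alone). Of the interferon response genes, 29 of 60 measured members rose (41 adjusted over the list alone), with Oas3 (2.87, SE 0.52), Mx1 (2.37, SE 0.44) and Stat1 (0.68, SE 0.16). Of the kidney injury genes, 7 of 19 measured members rose (9 adjusted over the list alone), with Havcr1 (log2 fold change 5.18, SE 1.15, adjusted p = 0.0219) and Timp1 (3.46, SE 0.60). Genes of fatty acid oxidation had 5 down of 34 (9 adjusted over the list alone), with Cyp4a14 (-1.86, SE 0.27) down. Inmt (-2.86, SE 0.28), a methyltransferase, and Kl (-1.21, SE 0.16), the ageing-related Klotho, fell. The mitochondrially encoded genes had 7 down of 9 (9 adjusted over the list alone), in libraries where Lars2 changed by -5.47 (SE 1.04, adjusted p = 0.0133). Without Young 1, the library with the gut and endocrine transcripts, 213 genes passed, and 375 did with the share of reads outside genes as a covariate, a fit added after the data were seen, as were the fits without all libraries holding transcripts of other organs.

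In Liver, genes of acute phase, macrophages and cell division were among the rises (n = 3 per group). Of the acute phase genes, 10 of 20 measured members rose (13 adjusted over the list alone), with Cp (log2 fold change 2.11, SE 0.36, adjusted p = 0.00371), the copper carrier ceruloplasmin, and Saa3 (2.77, SE 0.59). Of the macrophage markers, 10 of 22 measured members rose (16 adjusted over the list alone), with Ms4a7 (4.35, SE 0.81) and Lgals3 (1.82, SE 0.31). Cdkn2a (log2 fold change 4.2, SE 0.80, adjusted p = 0.00611), the cell cycle inhibitor p16, rose in a senescence list where 5 of 13 measured members rose (6 adjusted over the list alone). Of the proliferation genes, 6 of 27 measured members rose (15 adjusted over the list alone), with Mki67 (1.67, SE 0.45). Male-biased liver genes had 0 up and 5 down of 16 (1 and 11 adjusted over the list alone) and female-biased ones 5 up and 2 down of 23 (9 and 2 adjusted over the list alone). Of the former, Hsd3b5 (log2 fold change -6.11, SE 0.53, adjusted p = 0.000447) and Slco1a1 (-5.73, SE 0.68), an organic anion transporter, fell, the latter from 147 ± 27.6 CPM (SD, n = 3) in Young to 2.77 ± 1.68 CPM (SD, n = 3) in Old libraries. Ckm (-5.70, SE 1.10), a skeletal muscle enzyme, fell from 7.71 ± 6.6 CPM (SD, n = 3) in Young libraries, but had a log2 fold change of 0.41 with the share of reads outside genes as a covariate. The interferon list had 2 up of 57 (0 adjusted over the list alone), and the mitochondrially encoded genes had 6 down of 9 (8 adjusted over the list alone). The Liver count was 1099 without Old 2 and 16 with the share of reads outside genes as a covariate, which was 36.7 to 83.4% in Young and 7.35 to 20% in the other Liver libraries.

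In Blood, red cell transcripts rose and B cell transcripts fell (n = 2 Old and 3 Young). Apol11b (log2 fold change 4.72, SE 0.40, adjusted p = 0.000935), of the apolipoprotein L family, was at 6620 ± 2370 CPM (SD, n = 2) in Old and 251 ± 63.1 CPM (SD, n = 3) in Young libraries. Of the erythroid genes, 12 of 17 measured members rose (15 adjusted over the list alone), with Slc4a1 (2.95, SE 0.39), the anion exchanger of red cells. Of the B cell markers, 16 of 16 measured members fell (16 adjusted over the list alone), with Cd79a (-1.93, SE 0.30) and Bank1 (-2.04, SE 0.38). Among interferon response genes, 15 of 59 measured members rose (21 adjusted over the list alone), with Oas3 (2.25, SE 0.36), Rsad2 (2.55, SE 0.47), Irf7 (2.01, SE 0.54) and Stat1 (0.89, SE 0.25). Gzmk (6.91, SE 0.90), a granzyme of cytotoxic lymphocytes, rose, while Ccr7 (-3.07, SE 0.48) and Lef1 (-4.09, SE 1.10) of naive T cells fell, with thymic Rag1 present in Young 2. Immediate early genes had 1 up and 10 down of 22 (1 and 11 adjusted over the list alone), with Fos (-3.0, SE 0.43). The Blood count was 380 without Old 2, 2459 without Young 1 and 0 by edgeR with the share of reads outside genes as a covariate.

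In Lung, macrophage and red cell genes were among the rises, and immediate early and matrix genes among the falls (n = 2 Old and 3 Young). Tlr7 (log2 fold change 1.94, SE 0.25, adjusted p = 0.007), a receptor for single-stranded RNA, rose in the list of innate immune receptors, where 8 of 41 measured members rose (11 adjusted over the list alone). Of the macrophage markers, 8 of 23 measured members rose (15 adjusted over the list alone), with Ctss (1.5, SE 0.25), and of the interferon response genes, 6 of 60 measured members rose (9 adjusted over the list alone), with Rsad2 (2.94, SE 0.69). Ighg2c (5.18, SE 1.04), an antibody heavy chain, rose, and of the erythroid genes, 4 of 14 measured members rose (12 adjusted over the list alone), with Slc4a1 (4.08, SE 0.82). Immediate early genes had 12 down of 27 (14 adjusted over the list alone), with Fos (log2 fold change -2.98, SE 0.44, adjusted p = 0.0153) at 27.9 ± 12.7 CPM (SD, n = 2) in Old and 222 ± 48.5 CPM (SD, n = 3) in Young libraries. Of the matrix genes, 6 of 35 measured members fell (11 adjusted over the list alone), with Col6a3 (-1.90, SE 0.20). Lars2 changed by -8.52 (SE 1.49, adjusted p = 0.021). The count was 5 without Old 2, 1974 without Young 2, the library with thymic Rag1, and 181 with the share of reads outside genes as a covariate.

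In Skin, the keratinocyte list rose and the skeletal muscle and erythroid lists fell by the camera test, but not with an estimated correlation (n = 2 Old and 3 Young). Grhl3 (log2 fold change 3.28, SE 0.52, adjusted p = 0.0406), a transcription factor of the epidermal barrier, and Il1a (3.88, SE 0.80) rose, and keratinocyte markers had 1 up of 20 (16 adjusted over the list alone). Tnnt1 (log2 fold change -6.71, SE 1.19, adjusted p = 0.0435), slow troponin, fell. Skeletal muscle markers had 1 down of 22 (18 adjusted over the list alone), erythroid genes 4 down of 13 (8 adjusted over the list alone) and oxidative phosphorylation genes 5 down of 51 (42 adjusted over the list alone), in a tissue where libraries of every condition held skeletal myosin. Inmt (-4.33, SE 0.37) and Retnla (-4.28, SE 0.82), a resistin-like protein, fell too. The count was 0 by edgeR without Old 1, 2287 without Young 1 and 1 with the share of reads outside genes as a covariate. In Heart, Ccl8 (log2 fold change 3.88, SE 0.38, adjusted p = 0.016), a monocyte chemokine, was the only gene to pass, at 52.5 ± 5.48 CPM (SD, n = 3) in Old and 3.57 ± 1.45 CPM (SD, n = 3) in Young libraries, while 1126 genes had an unadjusted p under 0.05 and DESeq2 called 117. By edgeR 0 passed without Old 2, Old 3, Young 2 or Young 3. In Muscle, Smoc1 (log2 fold change 2.28, SE 0.27, adjusted p = 0.0383), a calcium-binding matrix protein, rose, and the 6 falls included Lars2 (-8.36, SE 0.86), AY036118 (-4.30, SE 0.52) and Gphn (-4.54, SE 0.34). Muscle had 192 calls without Old 2, 3 without Young 1 and 831 with the covariate, against 2986 genes at an unadjusted p under 0.05.

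The series title names Stat1 and interferon signalling, and the list of interferon response genes was tested in each tissue. Its median log2 fold change from Young to Old was 1.56 in Brain, 0.76 in Kidney, 0.74 in Muscle, 0.61 in Blood, 0.34 in Lung and 0.25 in Heart, all past the camera test. The Skin median was -0.43, past the test in the other direction, and 0.51 with the share of reads outside genes as a covariate. Liver had 0.16 (adjusted p = 0.0864), not past it. With an estimated correlation between genes none of these calls held (smallest adjusted p = 0.315, in Brain). Nor did any of the 202 list calls of this comparison. Of 60 interferon response genes, 43 differed between tissues (48 adjusted over the list alone). Irf7 (log2 fold change 2.01, SE 0.54, adjusted p = 0.0405), the regulator of interferon production, rose in Blood, with 1.78 (SE 0.38) in Brain and 1.61 (SE 0.38) in Kidney, whereas Skin had -1.68 (SE 0.39, adjusted p = 0.0563). For Irf7 (adjusted p = 0.000651) and Stat1 (adjusted p = 0.018) the change differed between tissues. That test lacked the covariate, so handling of Young libraries may contribute. Medians of 0.29 in Blood without Old 1 and -0.28 in Skin with the replicate block stayed past the test. That of -0.27 in Skin without Young 1 did not. In Lung the median was 0.89 with the covariate.

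**Figure D2:**
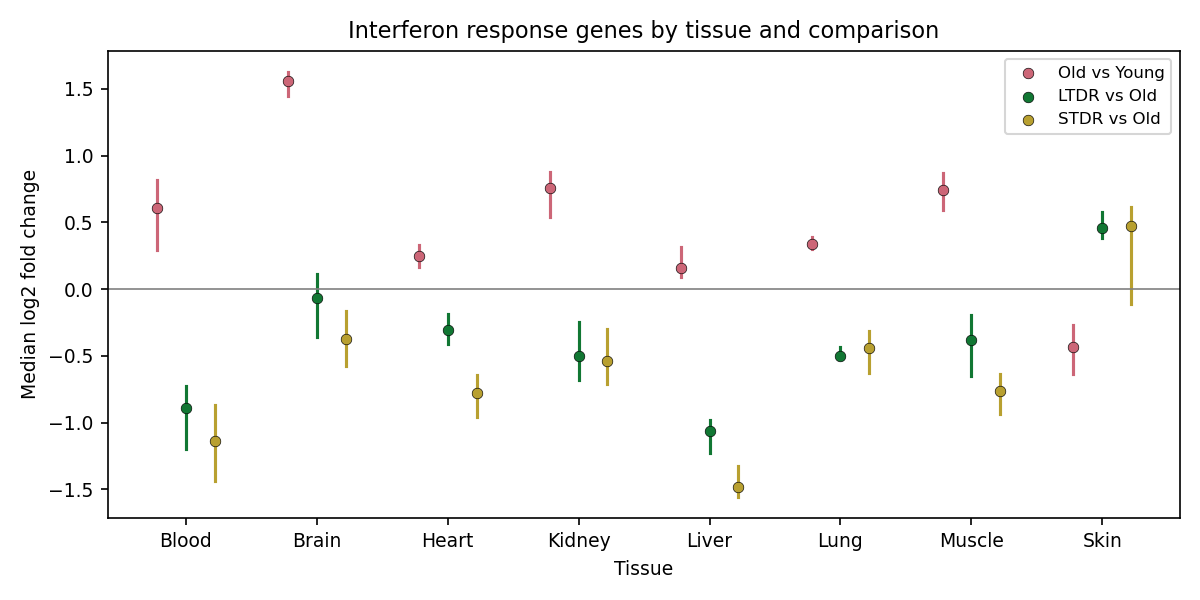
Median log2 fold change of the interferon response genes (57 to 60 measured genes) in each tissue, for Old against Young, LTDR against Old and STDR against Old. Points are list medians and bars the lowest and highest median when 1 library was left out; in Liver the 3 medians were 0.16, -1.06 and -1.48.

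The comparison of LTDR with Old mice addresses which transcripts differ with food restriction through adult life at the same age. As a list, circadian clock genes rose past the camera test in all tissues but Brain, with medians of 0.45 in Blood to 1.52 in Liver. Per2 and Per3, repressors of the circadian clock, and Tef, a clock-controlled transcription factor, rose in Kidney, Liver and Lung. In Liver Per3 (log2 fold change 4.88, SE 0.38, adjusted p = 3.69e-05) was at 59.9 ± 18.9 CPM (SD, n = 3) in LTDR and 1.99 ± 0.386 CPM (SD, n = 3) in Old libraries, and Dbp (5.47, SE 0.57) and Usp2 (4.56, SE 0.29) rose with it. Per2 (log2 fold change 3.17, SE 0.34, adjusted p = 0.00207) and Dbp (3.53, SE 0.60) rose in Kidney, where Npas2 (-3.49, SE 0.38), a relative of Clock, fell. Arntl (log2 fold change -2.47, SE 0.30, adjusted p = 0.0244), the core activator Bmal1, fell in Lung while Per2 (2.64, SE 0.34) and Tef (1.66, SE 0.22) rose. Of the circadian clock genes, 18 up and 4 down of 23 (18 and 4 adjusted over the list alone) changed in Liver, 10 up and 1 down of 23 (18 and 3 adjusted over the list alone) in Kidney and 3 up and 1 down of 23 (13 and 4 adjusted over the list alone) in Lung. The calls in these 3 tissues held with an estimated correlation (adjusted p = 0.0093, 0.0093 and 0.0401 in Kidney, Liver and Lung) and were the only 3 of 182 list calls that did.

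**Figure D3:**
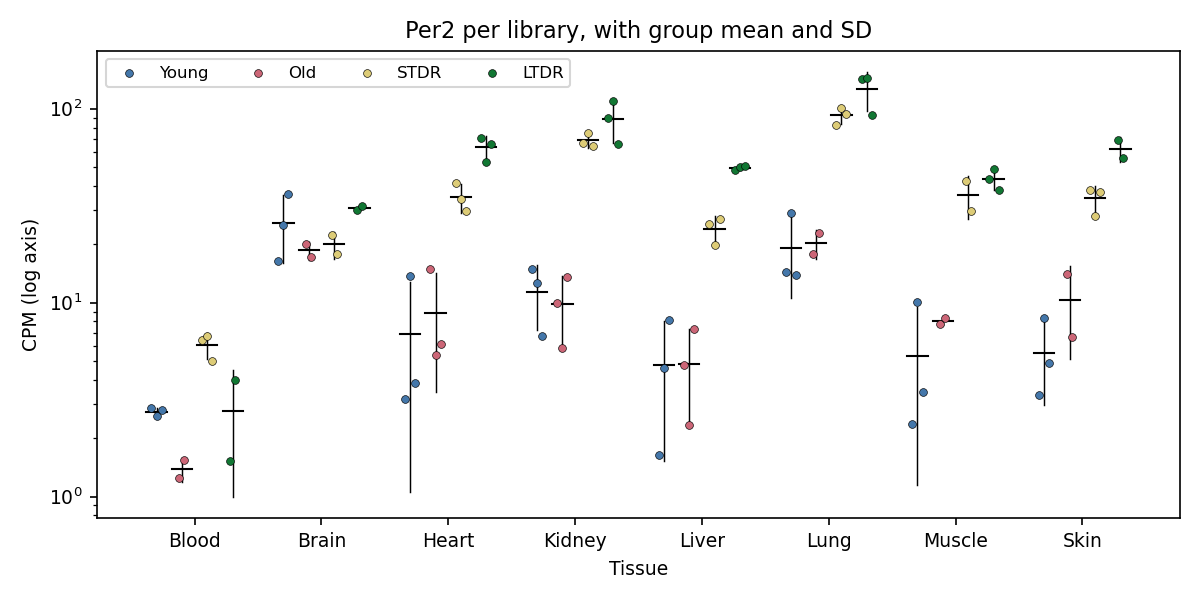
Per2 in CPM on a log axis in each library of the 8 tissues, by condition. Points are libraries and bars group means with SD; in Kidney the LTDR mean of 88.3 CPM lies above the Old mean of 9.83 CPM.

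Liver carried most of the changes, with 4762 genes (2407 up and 2355 down, n = 3 per group). Mup10 (log2 fold change -7.58, SE 0.73, adjusted p = 0.000134), a major urinary protein, fell to 4.29 ± 2.08 CPM (SD, n = 3) in LTDR from 818 ± 350 CPM (SD, n = 3) in Old libraries. Genes of this family are near-identical copies, so reads could be split between them. For the interferon list, 0 of 57 measured members rose and 38 fell (1 and 44 adjusted over the list alone), with Oasl1 (-3.19, SE 0.36), Cmpk2 (-1.91, SE 0.22) and Ifit3 (-1.44, SE 0.29). Of the macrophage markers, 1 of 22 measured members rose and 12 fell (1 and 17 adjusted over the list alone), with Lyz2 (-2.52, SE 0.47), and of the acute phase genes, 17 of 20 measured members fell (17 adjusted over the list alone), with Orm1 (-1.82, SE 0.21) and Cp (-1.95, SE 0.36). Matrix genes had 1 up and 17 down of 34 (1 and 20 adjusted over the list alone), with Lox (-4.05, SE 0.74), a collagen cross-linking enzyme, and Lum (-2.07, SE 0.36). Of the proliferation genes, 16 of 27 measured members fell (17 adjusted over the list alone), with Mki67 (-1.93, SE 0.44). Cdkn1a (-2.84, SE 0.74), the cell cycle inhibitor p21, fell. Genes of xenobiotic metabolism had 13 up and 2 down of 33 (14 and 2 adjusted over the list alone), with Por (2.23, SE 0.20), the electron donor of cytochromes P450, and Cyp2e1 (2.46, SE 0.23). Fatty acid oxidation genes had 13 up and 1 down of 32 (14 and 2 adjusted over the list alone), with Acadl (1.26, SE 0.19). The count was 3148 without LTDR 3.

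Kidney had 143 genes (72 up and 71 down, n = 3 per group). Hmgcs2 (log2 fold change 2.74, SE 0.47, adjusted p = 0.0277), the rate-limiting enzyme of ketone synthesis, rose, in a list of fatty acid oxidation and ketogenesis where 5 of 34 measured members rose and 0 fell (10 and 1 adjusted over the list alone), with Cyp4a14 (2.06, SE 0.27). Inmt (log2 fold change 3.17, SE 0.28, adjusted p = 0.00131) was at 215 ± 19.1 CPM (SD, n = 3) in LTDR and 23.9 ± 7.68 CPM (SD, n = 3) in Old libraries. Hdc (-5.59, SE 0.79), which makes histamine, Timp1 (-3.12, SE 0.60) and Ccl7 (-4.13, SE 0.72) fell. In the interferon list, 2 of 60 measured members fell (16 adjusted over the list alone), with Mx1 (-2.25, SE 0.44), and of the matrix genes, 3 of 35 measured members fell (13 adjusted over the list alone), with Col3a1 (-1.52, SE 0.24). The count was 34 without LTDR 2.

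Few single genes passed elsewhere. Heart had 3 falls, Spon2 (log2 fold change -2.55, SE 0.31, adjusted p = 0.0468), a secreted matrix protein, Hist1h1b (-1.30, SE 0.16), a linker histone, and Glipr2 (-0.95, SE 0.11). Lung had 10 genes, among them Lamc3 (1.76, SE 0.24) and Lama2 (1.15, SE 0.16), laminin chains, which rose. Skin had 1, Inmt at 49.8 ± 7.07 CPM (SD, n = 2) in LTDR and 3.39 ± 1.65 CPM (SD, n = 2) in Old libraries. Calls by edgeR numbered 0 in Blood, Brain and Muscle, with 1568, 2659 and 2314 genes at an unadjusted p under 0.05 and 218, 593 and 547 calls by DESeq2. In Muscle, oxidative phosphorylation genes had 0 calls over all genes and 46 of 51 rises adjusted over the list alone (median 0.88, adjusted p = 0.463 with an estimated correlation). In Blood, B cell markers had 0 and 15 of 16 (median 1.35, adjusted p = 0.317 with an estimated correlation). Leaving out 1 library gave 221 calls in Muscle without Old 2, 0 in Heart without any 1 library, 0 in Lung without LTDR 2 and 0 in Skin without LTDR 2, Old 1 or Old 2. With the share of reads outside genes as a covariate, Heart had 95.

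The interferon list had a median of -1.06 in Liver, -0.89 in Blood, -0.50 in Lung, -0.50 in Kidney, -0.38 in Muscle and -0.31 in Heart, each past the camera test. Skin had 0.46, past it in the other direction, and Brain -0.07 (adjusted p = 0.183), or -0.36 and past it without LTDR 1 and 0.11 and not past it without LTDR 2. With an estimated correlation the smallest adjusted p = 0.317, in Blood and Lung. Member genes adjusted over the list alone fell in number by tissue, 44 in Liver, 24 in Lung, 21 in Blood and 16 in Kidney, against 38, 0, 0 and 2 over all genes. Of 60 interferon response genes, 25 differed between tissues (38 adjusted over the list alone), with Irf7 at adjusted p = 0.000363. Irf7 itself had -2.29 (SE 0.63, adjusted p = 0.26) in Blood and 2.45 (SE 0.42, adjusted p = 0.575) in Skin. The Kidney median was -0.25 without Old 3, the Heart median -0.19 without Old 2 and the Muscle median -0.20 without LTDR 2, all still past the test.

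The comparison of STDR with Old mice addresses the response to 2 months of restriction late in life. By the camera test glucocorticoid targets rose in 7 tissues and clock genes in 6, but of 173 list calls only 2 held with an estimated correlation, clock genes in Liver and lipogenesis genes in Muscle. Rtp4, an interferon-induced chaperone, and Serpinh1, the collagen chaperone, each fell in 5 tissues. Inmt rose in Heart, Kidney, Liver and Skin, where it reached 137 ± 26.3 CPM (SD, n = 3) in STDR against 3.39 ± 1.65 CPM (SD, n = 2) in Old libraries. Genes passing the test numbered 3574 in Liver (1618 up and 1956 down), 2888 in Blood (1033 and 1855), 1338 in Brain (810 and 528) and 670 in Kidney (312 and 358). Heart had 404 (180 and 224), Muscle 185 (60 and 125), Lung 174 (103 and 71) and Skin 7.

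In Liver, lipid synthesis, interferon and division genes fell while fat oxidation genes rose (n = 3 per group). Cyp4a14 (log2 fold change 4.71, SE 0.76, adjusted p = 0.00256), a fatty acid hydroxylase induced by fasting, was at 2780 ± 337 CPM (SD, n = 3) in STDR and 106 ± 84.4 CPM (SD, n = 3) in Old libraries. Fatty acid oxidation genes had 15 up and 1 down of 32 (18 and 1 adjusted over the list alone), and lipogenesis genes had 11 down of 23 (14 adjusted over the list alone), with Acly (-2.09, SE 0.32), Thrsp (-3.28, SE 0.49) and Pnpla3 (-5.92, SE 0.89). Of the cholesterol synthesis genes, 12 of 24 measured members fell (13 adjusted over the list alone), with Mvd (-2.25, SE 0.46). Of the interferon response genes, 45 of 57 measured members fell (49 adjusted over the list alone), with Cmpk2 (log2 fold change -2.36, SE 0.23, adjusted p = 0.000122), Irf7 (-1.50, SE 0.30) and Stat1 (-1.31, SE 0.25). The sensor genes Zbp1 (-2.99, SE 0.42) and Ifih1 (-1.70, SE 0.17) fell in a list of innate immune receptors where 14 of 38 measured members fell (17 adjusted over the list alone). Of the proliferation genes, 20 of 27 measured members fell (21 adjusted over the list alone), and of the endoplasmic reticulum chaperones, 0 of 27 measured members rose and 12 fell (1 and 14 adjusted over the list alone), with Calr (-1.56, SE 0.29). Clock genes had 14 up and 1 down of 23 (15 and 2 adjusted over the list alone), with Per2 (2.30, SE 0.42) (adjusted p = 0.0392 for the list with an estimated correlation). Fkbp5 (1.57, SE 0.23), a glucocorticoid target, rose, and Mup10 (-6.89, SE 0.71) fell. The count was 2244 without Old 2.

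In Blood, interferon, red cell, cytotoxic and division genes fell, and B cell genes rose (n = 3 STDR and 2 Old). Apol11b (log2 fold change -4.48, SE 0.40, adjusted p = 0.000308) was at 296 ± 68.4 CPM (SD, n = 3) in STDR and 6620 ± 2370 CPM (SD, n = 2) in Old libraries. Among interferon response genes, 1 of 59 measured members rose and 29 fell (2 and 35 adjusted over the list alone), with Irf7 (-3.76, SE 0.57), Ifit1 (-3.94, SE 0.51), Oasl2 (-4.00, SE 0.69) and Stat1 (-1.63, SE 0.25). Of the erythroid genes, 15 of 17 measured members fell (15 adjusted over the list alone), and of the B cell markers, 14 of 16 measured members rose (14 adjusted over the list alone), with Cd79a (2.54, SE 0.30). Cytotoxic markers had 10 down of 14 (13 adjusted over the list alone), with Prf1 (-3.07, SE 0.35), the pore-forming perforin, and Eomes (-3.11, SE 0.52). Of the proliferation genes, 20 of 32 measured members fell (23 adjusted over the list alone). Clock genes had 6 up of 19 (8 adjusted over the list alone), with Per1 (2.04, SE 0.30). Col3a1 (6.03, SE 1.53), a collagen of fibroblasts, also rose. The count was 1108 without Old 1 and 380 with the share of reads outside genes as a covariate.

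In Heart, fuel genes were among the rises and matrix, division and immune genes among the falls (n = 3 per group). Pdk4 (log2 fold change 2.51, SE 0.51, adjusted p = 0.0399), which shuts glucose oxidation, was at 827 ± 404 CPM (SD, n = 3) in STDR and 146 ± 69.3 CPM (SD, n = 3) in Old libraries. Fatty acid oxidation genes had 5 up of 31 (20 adjusted over the list alone), with Acot1 (2.22, SE 0.40) and Ucp3 (2.41, SE 0.52). Of the matrix genes, 11 of 35 measured members fell (23 adjusted over the list alone), with Col1a1 (-2.02, SE 0.31) and Col3a1 (-2.21, SE 0.28), and of the proliferation genes, 12 of 33 measured members fell (24 adjusted over the list alone), with Top2a (-2.60, SE 0.31). Nppb (log2 fold change -2.31, SE 0.52, adjusted p = 0.0481), a natriuretic peptide of wall stress, fell. For the interferon list, 11 of 60 measured members fell (42 adjusted over the list alone), with Gbp4 (-1.64, SE 0.29), Rtp4 (-1.38, SE 0.25) and Stat1 (-0.78, SE 0.17), and the chemokines Ccl7 (-2.96, SE 0.43) and Ccl8 (-1.72, SE 0.34) fell. The Heart count was 22 without STDR 2, 1493 without STDR 1 and 1675 with the share of reads outside genes as a covariate.

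In Kidney, clock and fat oxidation genes were among the rises, with liver albumin in STDR 1 (n = 3 per group). Hmgcs2 (log2 fold change 3.11, SE 0.48, adjusted p = 0.00756) was at 301 ± 96.2 CPM (SD, n = 3) in STDR and 34.8 ± 20.3 CPM (SD, n = 3) in Old libraries, and Cyp2e1 (3.47, SE 0.61) and Apoc3 (3.11, SE 0.53) rose. Fatty acid oxidation and ketogenesis genes had 13 up and 0 down of 34 (13 and 1 adjusted over the list alone) and hepatocyte markers 3 up of 17 (14 adjusted over the list alone). Clock genes had 10 up and 0 down of 23 (14 and 1 adjusted over the list alone), with Per2 (2.80, SE 0.33), and glucocorticoid targets had 4 up of 20 (10 adjusted over the list alone), with Tsc22d3 (1.81, SE 0.36). Gatm (log2 fold change -2.41, SE 0.22, adjusted p = 0.000881), the first enzyme of creatine synthesis, Nphs2 (-2.47, SE 0.26), podocin of the filtration barrier, and Epo (-4.24, SE 0.85), erythropoietin, fell. In the interferon list, 12 of 60 measured members fell (26 adjusted over the list alone), with Ifit1 (-1.46, SE 0.24) and Stat1 (-0.87, SE 0.16). Without Kidney STDR 1 and Young 1 together 277 genes passed, and 179 did without Old 2.

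In Muscle, lipid synthesis genes were among the falls (n = 2 per group). Fasn (log2 fold change -4.43, SE 0.77, adjusted p = 0.0443), fatty acid synthase, was at 483 ± 118 CPM (SD, n = 2) in STDR and 10400 ± 1750 CPM (SD, n = 2) in Old libraries, and Acly (-4.18, SE 0.70), Acaca and Dgat2 (-3.14, SE 0.40) fell. Of the lipogenesis genes, 10 of 23 measured members fell (17 adjusted over the list alone) (adjusted p = 0.0392 with an estimated correlation). Adrb3 (-4.43, SE 0.72), the adrenergic receptor of fat cells, fell in an adipocyte list where 1 of 18 measured members fell (13 adjusted over the list alone), and of the matrix genes, 6 of 35 measured members fell (11 adjusted over the list alone). Mb (log2 fold change 2.78, SE 0.39, adjusted p = 0.0248), myoglobin, and Myl2 (4.22, SE 0.66) rose among the slow and oxidative fibre genes, where 3 up and 0 down of 16 (9 and 2 adjusted over the list alone) changed. Hoxc10 (6.22, SE 0.93), a gene of hindlimb position, rose from 0.122 ± 0.00172 CPM (SD, n = 2) in Old libraries. Neutrophil markers had 0 calls over all genes and 11 of 15 rises adjusted over the list alone, with a median of 5.91. Organs were cut into pieces and Old 1 held salivary Psp, so restriction was not separated from the tissue sampled. Leaving out Muscle Young 1, Young 2, Old 1 and STDR 1, the libraries with transcripts of other organs, left STDR and Old with 1 library each. The calls therefore could not be tested again in replicated groups without those libraries.

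In Brain, oxidative phosphorylation and myelin genes were among the rises and endothelial markers among the falls (n = 2 per group). Chat (log2 fold change 3.83, SE 0.86, adjusted p = 0.046), which makes acetylcholine, was at 33.6 ± 10.4 CPM (SD, n = 2) in STDR and 2.36 ± 1.39 CPM (SD, n = 2) in Old libraries, and Ntrk1 (4.07, SE 0.96) and Gal (4.56, SE 0.82) rose with it. Oxidative phosphorylation genes had 18 up and 0 down of 51 (42 and 1 adjusted over the list alone), with Cox5a (1.13, SE 0.17), and myelin genes had 6 up of 19 (12 adjusted over the list alone), with Mog (1.32, SE 0.19). Glucocorticoid targets had 6 up of 20 (8 adjusted over the list alone), with Fkbp5 (1.14, SE 0.21) and Mt2 (1.84, SE 0.23). Endothelial markers had 0 up and 5 down of 14 (1 and 9 adjusted over the list alone), with Cldn5 (-1.0, SE 0.17) down, and class II genes had 2 down of 10 (4 adjusted over the list alone), with H2-Ab1 (-2.19, SE 0.44). Hindbrain and spinal cord genes had a median log2 fold change of 2.35 (median absolute deviation 0.56) with 0 of 18 past the threshold, forebrain genes -0.8 (1.11) with 0 of 21, and genes of all neurons 0.62 (0.37) with 12 of 21 up. The interferon list had 2 down of 58 (0 adjusted over the list alone). By edgeR the count was 0 without STDR 2 and 3334 without STDR 1.

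In Lung, glucocorticoid targets were among the rises (n = 3 STDR and 2 Old). Zbtb16 (log2 fold change 2.51, SE 0.44, adjusted p = 0.0381), a glucocorticoid-induced transcription factor, was at 164 ± 45.3 CPM (SD, n = 3) in STDR and 28.8 ± 5.35 CPM (SD, n = 2) in Old libraries, and Hif3a (2.81, SE 0.51) and Per2 (2.18, SE 0.33) rose. Glucocorticoid targets had 6 up of 20 (13 adjusted over the list alone), and interferon genes had 4 down of 60 (11 adjusted over the list alone), with Isg15 (-1.44, SE 0.28) and Ifi44 (-1.85, SE 0.36). The Lung count was 0 by edgeR without Old 1. In Skin, Inmt (log2 fold change 5.32, SE 0.38, adjusted p = 0.00229) and Hbb-b1 (3.57, SE 0.37), beta globin, rose, and Eln (-2.59, SE 0.31), elastin, Carns1 (-3.76, SE 0.48) and Adamts10 (-1.75, SE 0.22) fell. The Skin count was 200 without STDR 1 and 2 without STDR 2, the library with testis transcripts.

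The interferon medians under short restriction were -1.48 in Liver, -1.14 in Blood, -0.78 in Heart, -0.76 in Muscle, -0.54 in Kidney, -0.44 in Lung and -0.37 in Brain, each past the camera test. Skin had 0.47, past it in the other direction, 0.38 and no longer past it without Old 1, and -0.11 without STDR 3. With an estimated correlation the smallest adjusted p = 0.384, in Liver. Of 60 interferon response genes, 38 differed between tissues (38 adjusted over the list alone), with Stat1 at adjusted p = 1.33e-05 and Irf7 at adjusted p = 2.47e-06. Stat1 itself fell in Blood with -1.63 (SE 0.25), Liver with -1.31 (SE 0.25), Kidney with -0.87 (SE 0.16) and Heart with -0.78 (SE 0.17), and had -0.08 (SE 0.16, adjusted p = 0.79) in Brain and 0.44 (SE 0.28, adjusted p = 0.378) in Skin. The Brain median was -0.16 without STDR 2, no longer past the test, and the Kidney median -0.30 without Old 3.

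**Figure D4:**
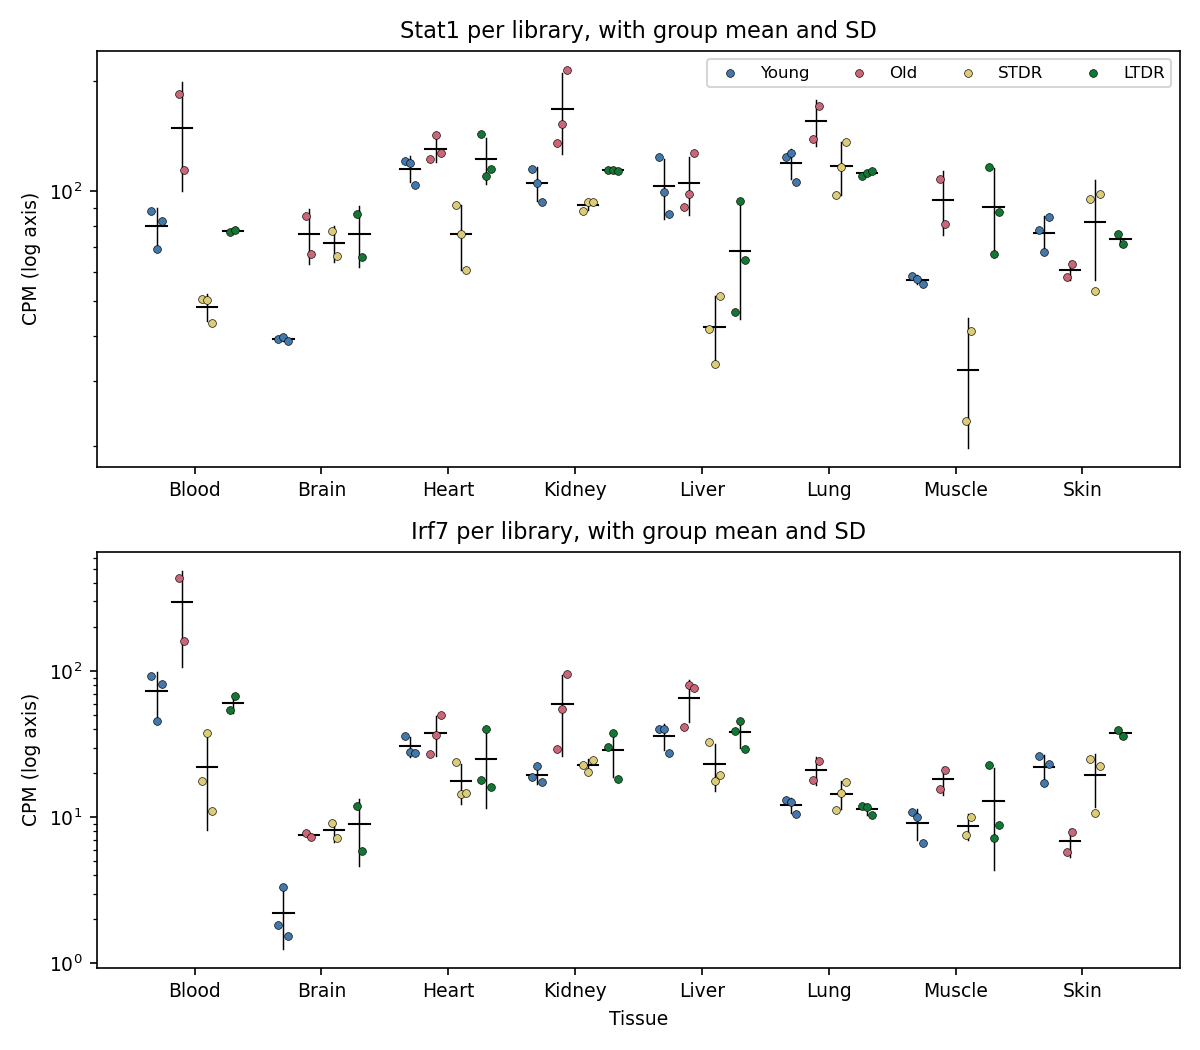
Stat1 (upper row) and Irf7 (lower row) in CPM on a log axis in each library of the 8 tissues, by condition. Points are libraries and bars group means with SD; the fall of Stat1 from Old to STDR passed in Blood, Heart, Kidney and Liver.

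The comparison of LTDR with STDR mice sets the 2 lengths of restriction side by side. Liver had 1089 genes (657 higher and 432 lower in LTDR), Blood 764 (562 and 202) and Muscle 577 (400 and 177). Kidney had 96 and Heart 20. Cdkn1a (log2 fold change -3.90, SE 0.74, adjusted p = 0.0151) and Fkbp5 (-1.20, SE 0.23) were lower in LTDR than in STDR Liver, and Stat1 (log2 fold change 1.49, SE 0.30, adjusted p = 0.0371) was higher in LTDR than in STDR Muscle. Named after their values were seen, U4 in Brain and Emp1 in Lung were the only genes to pass there. Skin had 0 by edgeR, with 2206 genes at an unadjusted p under 0.05 and 342 calls by DESeq2. The Blood count was 5 without LTDR 2, the Heart count 2092 without STDR 1, the Kidney count 4 without LTDR 2, the Liver count 264 without LTDR 1 and the Brain count 1267 without STDR 1. By edgeR 0 Muscle genes passed without LTDR 2.

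Liver genes opposed between age and restriction numbered 1284 with LTDR (60.2% of the age calls) and 780 with STDR (36.6%). Another 31 and 59 changed the same way. Cyp2b13 (4.65, SE 0.92), a cytochrome P450, rose with LTDR after a log2 fold change of -5.15 (SE 0.94) with age. In Blood, 1348 genes (82.6%) were opposed with STDR. Brain had 460 with STDR, against 50 that changed the same way. Kidney had 49 with LTDR, against 0, but 64 with STDR against 65 that changed the same way, and Lung had 4 and 61, against 0 in both. Independent lists of the same sizes would share 147 and 204 genes in Liver with LTDR (up then down, down then up) and 168 and 30 in Blood with STDR. Counts simulated from the Old means with no gene changed gave 0 in both, but hardly any gene passes there. This 0 cannot show what shared Old libraries add to real changes. The fold changes correlated more negatively than simulated only in Blood, Liver and Skin with LTDR and Blood and Heart with STDR. Observed minus simulated covariance with LTDR was -0.957 in Blood, -0.184 in Brain, -0.119 in Kidney, -0.356 in Liver, -0.004 in Lung, -0.304 in Muscle and -0.232 in Skin, and of the other sign in Heart at 0.177. With STDR it was -1.188 in Blood, -0.174 in Brain, -0.348 in Heart, -0.035 in Kidney, -0.244 in Liver, -0.044 in Lung, -0.065 in Muscle and -0.387 in Skin. The 2 or 3 Old libraries per tissue were not split, as 1 part would hold only 1. Sharing them may cause part of the overlap. Genes raised with age in at least 2 other tissues had medians past the camera test in every tissue with LTDR, from -0.59 in Liver to -0.15 in Kidney and Lung and, in the other direction, 0.07 in Skin. With STDR they passed in 5 tissues, from -0.38 in Liver to -0.09 in Lung, but not in Brain (-0.04), Muscle (-0.05) or Skin (0.25). No call held with an estimated correlation (the smallest adjusted p = 0.0562, for LTDR in Heart and Lung). The same Old animals may define this list and be its reference, as tissues may share animals, so an effect of restriction is not separated.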

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

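Tests on Lars2 in Heart, on genes of all neurons and on macrophage markers were chosen after the results were seen.

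The change of 21 panel results differed between tissues by the test without a covariate, with adjusted p in brackets. For Old against Young these were Stat1 (0.018), Irf7 (0.000651), Ifit3 (0.000296), Oasl2 (7.93e-05), Bst2 (0.000695), H2-K1 (0.0214), Cd74 (0.000213) and Tlr7 (0.000666). Irf7 had a log2 fold change of 2.01 in Blood and -1.68 in Skin. For LTDR against Old they were Irf7 (0.000363), Ifit3 (0.000865), Oasl2 (0.00269) and Bst2 (0.0289), with Irf7 at -2.29 in Blood and 2.45 in Skin. For STDR against Old they were Stat1 (1.33e-05), Irf7 (2.47e-06), Ifit3 (3.17e-05), Oasl2 (0.00011), Bst2 (0.00176), H2-K1 (0.0215), Cd74 (0.0249), Tlr7 (0.00256) and Per2 (0.049). Stat1 had -1.63 in Blood and 0.44 in Skin, and Per2 had 2.80 in Kidney and 0.11 in Brain. No group had the 4 libraries that a test for a single distant library needs.

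Lars2 counts were higher in the Young libraries of Kidney, Liver, Lung, Muscle and Skin than in any other library of those tissues. A fall of Lars2 expression with age in every tissue is argued against by Heart, where its log2 fold change was 1 (SE 0.46). Reads from ribosomal RNA may explain the pattern, since within tissue and condition Lars2 followed AY036118, whose sequence is ribosomal, with Pearson r = 0.71 and Spearman rho = 0.65 over 86 libraries (permutation p = 1e-04, the smallest that 10000 permutations can give, and 2e-04, adjusted 2e-04 and 4e-04 for 2 relations). Without the 2 libraries farthest from the median r was 0.64. Lars2 and the share of reads outside genes had r = 0.31 (permutation p = 0.06), rho = 0.2 (permutation p = 0.2) and r = 0.13 without the 2 farthest libraries. Taken within groups, these values cannot test Young against other libraries. In Kidney, Liver, Lung, Muscle and Skin, but not Blood, Brain or Heart, every Young library had a higher share than any other. A difference in RNA handling may thus confound age there and stays open, since the labels give no batch.

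Forebrain genes were lower in Old than in Young Brain, with a median log2 fold change of -3.5 over 21 genes. Fewer neurons of every region is argued against as the whole cause, since genes of all neurons had a median of -0.86 (median absolute deviation 0.66), but 15 of 21 fell, so some loss stays open. Pieces from different brain regions could produce the pattern, as organs were cut into pieces, and cannot be told apart from other causes here. The bound written beforehand was a median of hindbrain and spinal cord genes under 0.2, and the value of 0.18 over 18 genes lay under it by less than its spread of 0.74. A change with age in the forebrain itself was not tested and stays open.

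Interferon response genes were lower in STDR than in Old libraries in 7 of 8 tissues. A single Old library with a high interferon response is argued against, since leaving out 1 Old library took the median to less than 50% of its value in 0 of 7 tissues. Fewer macrophages in STDR tissue cannot be told apart from lower expression per cell. The interferon median lay more than 0.3 below the macrophage median in 4 of 7 tissues, Blood, Brain, Liver and Muscle, but within 0.14 of it in Heart, Kidney and Lung. A response to restriction stays open, as do other cell types, which were not tested.

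Heart, Kidney and Liver, with 3 libraries per group, have 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. The value in brackets is the highest size in any other split, then the number of splits as large as the real one. Genes changed for Old against Young numbered 1 in Heart (0, 1 of 10), 1614 in Kidney (0, 1 of 10) and 2133 in Liver (0, 1 of 10). Genes changed for LTDR against Old numbered 3 in Heart (1484, 2 of 10), 143 in Kidney (0, 1 of 10) and 4762 in Liver (0, 1 of 10). Genes changed for STDR against Old numbered 404 in Heart (0, 1 of 10), 670 in Kidney (0, 1 of 10) and 3574 in Liver (3, 1 of 10). Genes changed for LTDR against STDR numbered 20 in Heart (5085, 2 of 10), 96 in Kidney (0, 1 of 10), 1089 in Liver (0, 1 of 10) and 1 in Lung (0, 1 of 10). The interferon median for Old against Young was 0.25 in Heart (0.29, 3 of 10), 0.76 in Kidney (0.61, 1 of 10) and 0.16 in Liver (0.41, 3 of 10). The interferon median for LTDR against Old was -0.31 in Heart (0.30, 1 of 10), -0.50 in Kidney (0.54, 2 of 10) and -1.06 in Liver (0.73, 1 of 10). The interferon median for STDR against Old was -0.78 in Heart (0.58, 1 of 10), -0.54 in Kidney (0.52, 1 of 10) and -1.48 in Liver (0.73, 1 of 10). The median of age-raised genes for LTDR against Old was -0.17 in Heart (0.10, 1 of 10), -0.15 in Kidney (0.13, 1 of 10) and -0.59 in Liver (0.47, 1 of 10). The median of age-raised genes for STDR against Old was -0.31 in Heart (0.22, 1 of 10), -0.18 in Kidney (0.14, 1 of 10) and -0.38 in Liver (0.42, 3 of 10). In Heart, 1 split with LTDR 1, LTDR 3 and Old 2 on one side called 1484 genes and 1 with LTDR 1, LTDR 3 and STDR 1 called 5085, several times the real counts, which points to a structure of the samples. Of the 6 libraries of each comparison, those on that side had the highest shares of reads outside genes, 21.1, 23.08 and 18.17% in the former and 21.1, 23.08 and 14.22% in the latter.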

How the results depend on the processing

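The fits with the share of reads outside genes as a covariate, and those without all Kidney or Muscle libraries holding at least 75 genes 4-fold above every other library of the tissue, were chosen after the data were seen. Counts are of genes past the adjusted threshold of 0.05 by edgeR unless DESeq2 is named, and a number in brackets after a 0 is the count at an unadjusted p under 0.05. Except where a sentence gives one, the cause of a change was not tested.

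RLE size factors left all 32 counts of changed genes within 1.5 times their value and all 24 interferon medians on their side of the test, and moved the median log2 fold change of all genes by at most 0.05. The 3 counts of genes differing between tissues stayed within 1.5 times under RLE size factors, no filter and limma voom with quality weights. Further fits were chosen after the data were seen. With same-numbered libraries of a condition as a block, quality-weighted counts were 8666, 1741 and 6609 for Old against Young, LTDR against Old and STDR against Old, beside 8624, 1728 and 6577 without it, at an estimated correlation within blocks of 0.003. Without quality weights the counts were 3822, 493 and 3129, or 3834, 493 and 3131 with the block, so they depend on the weights. DESeq2 left 7 of 32 counts within 1.5 times. DESeq2 counts outside that for Old against Young were 117 in Heart, 2548 in Kidney, 1767 in Lung, 1158 in Muscle and 2175 in Skin. For LTDR against Old they were 218 in Blood, 593 in Brain, 283 in Heart, 767 in Kidney, 141 in Lung, 547 in Muscle and 46 in Skin. For STDR against Old they were 2497 in Brain, 1387 in Heart, 1567 in Kidney, 951 in Lung, 1086 in Muscle and 1169 in Skin. For LTDR against STDR they were 567 in Brain, 1083 in Heart, 765 in Kidney, 1681 in Liver, 283 in Lung, 1797 in Muscle and 342 in Skin. Without the filter on low counts 19 of 32 counts stayed within 1.5 times, with more genes tested. Unfiltered counts outside that for Old against Young were 2 in Heart and 70 in Muscle. For LTDR against Old they were 339 in Blood, 95 in Brain, 1 in Heart, 21 in Lung and 14 in Muscle. For STDR against Old they were 219 in Heart and 14 in Skin. For LTDR against STDR they were 1678 in Blood, 57 in Brain, 159 in Kidney and 13 in Lung.

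With the share of reads outside genes as a covariate 3 of 14 counts stayed within 1.5 times. Covariate counts outside that for Old against Young were 0 (1754) in Blood, 37 in Heart, 375 in Kidney, 16 in Liver, 181 in Lung, 831 in Muscle and 1 in Skin. For LTDR against Old there were 95 in Heart, and for LTDR against STDR 115. For STDR against Old there were 380 in Blood and 1675 in Heart. Without the Kidney and Muscle libraries holding transcripts of other organs 4 of 8 counts stayed within 1.5 times, with fewer libraries. Outside that were 404 in Kidney and 4 in Muscle for Old against Young, and 277 and 23 for STDR against Old. In Liver the log2 fold change of Ckm for Old against Young was 0.41 with the covariate and -5.70 without it, a reversal.

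Leaving out 1 library kept 45 of 167 counts within 1.5 times. An arm left with 1 library was assumed to vary like the other groups. For Old against Young the 1631 Blood genes became 387 without Old 1, 380 without Old 2, 2459 without Young 1, 682 without Young 2 and 935 without Young 3. The 4815 Brain genes became 1988 without Old 2, 4683 without Young 2 and 3133 without Young 3. The 1 Heart gene became 2 without Old 1, 0 (717) without Old 2, 0 (1078) without Old 3, 0 (761) without Young 2 and 0 (666) without Young 3. The 1614 Kidney genes became 950 without Old 2, 395 without Old 3, 213 without Young 1, 1512 without Young 2 and 310 without Young 3. The 2133 Liver genes became 1099 without Old 2 or Young 2, 2420 without Old 3 and 1187 without Young 1. The 826 Lung genes became 9 without Old 1, 5 without Old 2, 62 without Young 1, 1974 without Young 2 and 99 without Young 3. The 7 Muscle genes became 192 without Old 2, 3 without Young 1, 105 without Young 2 and 4 without Young 3. The 311 Skin genes became 0 (2308) without Old 1, 1 without Old 2, 2287 without Young 1, 0 (2757) without Young 2 and 0 (3238) without Young 3.

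For LTDR against Old the 0 Blood genes became 0 (1413) without LTDR 1, 1 without Old 1 and 3 without Old 2. The 0 Brain genes became 0 (1574) without LTDR 1, 3 without LTDR 2, 9 without Old 1 and 1 without Old 2. The 3 Heart genes became 0 (909) without LTDR 1, 0 (3199) without LTDR 2, 0 (1279) without LTDR 3, 0 (1322) without Old 1, 0 (1940) without Old 2 and 0 (1164) without Old 3. The 143 Kidney genes became 88 without LTDR 1, 34 without LTDR 2, 94 without LTDR 3, 219 without Old 1, 42 without Old 2 and 67 without Old 3. The 4762 Liver genes became 3148 without LTDR 3 and 4586 without Old 3. The 10 Lung genes became 4 without LTDR 1, 0 (1013) without LTDR 2, 6 without LTDR 3, 1 without Old 1 and 0 (1004) without Old 2. The 0 Muscle genes became 0 (2178) without LTDR 1 and 221 without Old 2. The 1 Skin gene became 2 without LTDR 1, 0 (260) without LTDR 2, 0 (211) without Old 1 and 0 (241) without Old 2.

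For STDR against Old the 2888 Blood genes became 1108 without Old 1, 1301 without Old 2 and 3048 without STDR 2. The 1338 Brain genes became 387 without Old 1, 36 without Old 2, 3334 without STDR 1 and 0 (2966) without STDR 2. The 404 Heart genes became 69 without Old 1, 51 without Old 2, 88 without Old 3, 1493 without STDR 1, 22 without STDR 2 and 35 without STDR 3. The 670 Kidney genes became 300 without Old 1, 179 without Old 2, 636 without Old 3, 338 without STDR 1 and 273 without STDR 3. The 3574 Liver genes became 2244 without Old 2 and 3816 without Old 3. The 174 Lung genes became 0 (1899) without Old 1, 0 (2177) without Old 2, 7 without STDR 2 and 247 without STDR 3. The 185 Muscle genes became 2 without Old 1, 642 without Old 2, 0 (1980) without STDR 1 and 123 without STDR 2. The 7 Skin genes became 1 without Old 1 or Old 2, 200 without STDR 1, 2 without STDR 2 and 54 without STDR 3.

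For LTDR against STDR the 764 Blood genes became 59 without LTDR 1, 5 without LTDR 2, 227 without STDR 1, 1075 without STDR 2 and 74 without STDR 3. The 1 Brain gene became 20 without LTDR 1, 0 (1733) without LTDR 2, 1267 without STDR 1 and 7 without STDR 2. The 20 Heart genes became 0 (2149) without LTDR 1, 1655 without LTDR 2, 0 (2200) without LTDR 3, 2092 without STDR 1, 0 (2066) without STDR 2 and 0 (1883) without STDR 3. The 96 Kidney genes became 46 without LTDR 1, 4 without LTDR 2, 76 without STDR 1 and 8 without STDR 3. The 1089 Liver genes became 264 without LTDR 1, 413 without LTDR 2, 347 without LTDR 3, 505 without STDR 1, 459 without STDR 2 and 1161 without STDR 3. The 1 Lung gene became 0 (1243) without LTDR 1, 0 (1525) without LTDR 2, 22 without LTDR 3, 0 (2664) without STDR 1 and 0 (2249) without STDR 3. The 577 Muscle genes became 414 without LTDR 1, 0 (2678) without LTDR 2, 0 (3053) without LTDR 3, 141 without STDR 1 and 192 without STDR 2. The 0 Skin genes became 3 without LTDR 1 and 0 (806) without LTDR 2.

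Replicate numbers are shared between conditions of a tissue, and a block tested whether they pair libraries. In 32 comparisons the correlation of same-numbered libraries ranged from -0.83 to 0.68. It exceeded 0.1 for all numbers in 0 of 13 comparisons with 3 shared numbers, and in 0 was every library closest to its own number. With 2, both were closest in Blood and Skin STDR and Muscle LTDR against Old. With the block 10 of 32 counts stayed within 1.5 times. Block counts outside that for Old against Young were 652 in Blood, 2198 in Brain, 0 (861) in Heart, 91 in Lung, 3 in Muscle and 0 (3181) in Skin. For LTDR against Old they were 0 (1563) in Heart, 92 in Kidney, 5 in Lung and 0 (341) in Skin. For STDR against Old they were 1750 in Blood, 0 (3870) in Brain, 74 in Heart, 385 in Kidney, 0 (2421) in Lung, 0 (2220) in Muscle and 1 in Skin. For LTDR against STDR they were 18 in Blood, 7 in Heart, 61 in Kidney, 0 (1751) in Lung and 1 in Muscle. In Skin the interferon median of STDR against Old was 0.10 with the block, no longer past the test.

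Interferon medians past the test kept their direction in all but 2 of the values from the alternatives run. They reversed to 0.51 in Skin for Old against Young with the covariate and to -0.11 in Skin for STDR against Old without STDR 3. With the covariate, medians for Old against Young were 1.12 in Kidney, 0.89 in Lung and 1.01 in Muscle. The ranges that follow are over fits with 1 library left out. For Old against Young the medians ran 0.29 to 0.82 in Blood, 1.45 to 1.63 in Brain, 0.17 to 0.33 in Heart, 0.54 to 0.88 in Kidney, 0.093 to 0.32 in Liver, 0.30 to 0.39 in Lung, 0.59 to 0.87 in Muscle and -0.63 to -0.27 in Skin. For LTDR against Old the medians ran -1.20 to -0.72 in Blood, -0.36 to 0.11 in Brain, -0.41 to -0.19 in Heart, -0.68 to -0.25 in Kidney, -1.23 to -0.98 in Liver, -0.51 to -0.43 in Lung, -0.65 to -0.20 in Muscle and 0.39 to 0.57 in Skin. For STDR against Old the medians ran -1.44 to -0.87 in Blood, -0.57 to -0.16 in Brain, -0.96 to -0.64 in Heart, -0.71 to -0.30 in Kidney, -1.55 to -1.33 in Liver, -0.63 to -0.32 in Lung, -0.94 to -0.64 in Muscle and -0.11 to 0.61 in Skin. In Liver the median of Old against Young passed the test with 0.53 under the covariate, 0.23 without the filter on low counts, 0.25 without Old 1 and 0.32 without Young 1. In Brain that of LTDR against Old passed with -0.36 without LTDR 1. No longer past it were -0.27 in Skin for Old against Young without Young 1, -0.16 in Brain without STDR 2 and 0.38 in Skin without Old 1, both for STDR against Old. Medians that moved by over 1.5 times and stayed past it were, for Old against Young, 0.29 in Blood without Old 1, 0.89 in Lung with the covariate and -0.28 in Skin with the replicate block. For LTDR against Old they were -0.19 in Heart without Old 2, -0.25 in Kidney without Old 3, and -0.65 and -0.20 in Muscle without LTDR 1 and LTDR 2. For STDR against Old they were -0.57 in Brain without STDR 1 and -0.30 in Kidney without Old 3. With an estimated correlation all 22 calls were lost at unchanged medians, with adjusted p = 0.315 to 0.874. Medians without a call for Old against Young were 0.61 in Blood, 1.56 in Brain, 0.25 in Heart, 0.76 in Kidney, 0.34 in Lung, 0.74 in Muscle and -0.43 in Skin. For LTDR against Old they were -0.89 in Blood, -0.31 in Heart, -0.50 in Kidney, -1.06 in Liver, -0.50 in Lung, -0.38 in Muscle and 0.46 in Skin. For STDR against Old they were -1.14 in Blood, -0.37 in Brain, -0.78 in Heart, -0.54 in Kidney, -1.48 in Liver, -0.44 in Lung, -0.76 in Muscle and 0.47 in Skin. With fry, which does not compare a list with other genes, 15 calls were lost. Lost with fry, medians for Old against Young were 0.25 in Heart, 0.34 in Lung, 0.74 in Muscle and -0.43 in Skin. For LTDR against Old they were -0.89 in Blood, -0.31 in Heart, -0.50 in Kidney, -0.50 in Lung, -0.38 in Muscle and 0.46 in Skin. For STDR against Old they were -0.37 in Brain, -0.54 in Kidney, -0.44 in Lung, -0.76 in Muscle and 0.47 in Skin.

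Genes opposed between age and restriction were counted again from DESeq2 calls, which left 3 of 16 counts within 1.5 times. Opposed counts outside that for LTDR against Old were 214 in Blood, 423 in Brain, 29 in Heart, 318 in Kidney, 74 in Lung, 186 in Muscle and 26 in Skin. For STDR against Old they were 810 in Brain, 31 in Heart, 186 in Kidney, 335 in Lung, 287 in Muscle and 473 in Skin. Genes raised with age in other tissues lost all 13 calls with an estimated correlation at unchanged medians. Age-raised medians without a call for LTDR against Old were -0.25 in Blood, -0.22 in Brain, -0.17 in Heart, -0.15 in Kidney, -0.59 in Liver, -0.15 in Lung, -0.34 in Muscle and 0.075 in Skin. For STDR against Old they were -0.28 in Blood, -0.31 in Heart, -0.18 in Kidney, -0.38 in Liver and -0.095 in Lung. Without the interferon, antigen presentation and immune cell lists 14 of 16 stayed on their side. The exceptions, without a call, were 0.066 in Skin for LTDR and -0.25 in Blood for STDR against Old. Counting genes raised in at least 3 other tissues kept all 16.

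Of 199 log2 fold changes of named genes, 196 kept their direction and side of the threshold with RLE size factors, 196 with DESeq2, 169 without the filter on low counts and 131 with the replicate block. Of those refitted, 57 did so with the covariate and 31 without the Kidney and Muscle libraries holding transcripts of other organs, and 743 values did with 1 library left out. No longer past the threshold were 3, 0, 29, 68, 50, 19 and 329 of them in the same order, and only Ckm with the covariate reversed. Newly past it were 3 with DESeq2, 1 without the filter and 1 with a library left out.

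In simulated LTDR and Old libraries with 200 changed genes, edgeR recovered 84.7% of 4-fold changes in Kidney, 75.5% in Brain, 65% in Heart, 51% in Muscle, 23.2% in Blood and 3% in Skin. For 2-fold changes it recovered 44.9% in Brain, 33.3% in Kidney and 0 to 5.1% in the other 4.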

Other observations

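All tests in this part were chosen after the results were seen.

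Antibody variable genes differ between animals, and their profiles were compared between tissues. In 84 of 112 pairs of tissues within a condition (75%), same-numbered libraries correlated more in 99 variable genes than differently numbered ones, with a permutation p of 0.001, the smallest that 1000 permutations can give. The share was 92.9% in LTDR, 78.6% in Young, 64.3% in Old and 64.3% in STDR. A candidate explanation is that many same-numbered libraries of a condition come from 1 animal, which the labels do not state.

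Per2 and Per3 rose in LTDR Kidney, Liver and Lung and Arntl fell in Liver and Lung, and the remaining 5 tissues were tested for the same pattern. The median of genes in phase with Per genes exceeded that of genes in the opposite phase by over 0.5 in 5 of 5, with differences of 0.7 in Blood, 0.67 in Brain, 2.64 in Heart, 2.79 in Muscle and 1.83 in Skin. In Kidney, Liver and Lung they were 3.26, 5.38 and 3.01. For STDR against Old the differences were 0.79 in Blood, 0.47 in Brain, 1.87 in Heart, 1.46 in Kidney, 2.76 in Liver, 1.45 in Lung, 0.86 in Muscle and 0.64 in Skin. A shift of clock phase against the hour of sampling may explain this, as restricted animals were fed once daily in the morning. Yet with STDR the opposite-phase median of 3 genes was 0.32 in Blood (-0.02 with LTDR) and the Per-phase median -0.11 in Brain. These STDR sets did not part around 0. A change of level at a fixed phase was not tested. Sampling hours are not in the labels.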
